A study of Mus musculus with 11 samples.

How the data were processed

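RNA of 11 libraries from HSCs of C57BL/6 mouse livers at postnatal day 0 was measured by Smart-seq2 sequencing of 100 to 200 sorted cells each. Samples were grouped by their titles in the labels into FSC-A High (4 libraries), FSC-A Low (3) and unfractionated HSCs (4). The gated libraries and the unfractionated libraries come in different units and were kept apart throughout.

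The deposited gated files give 1 value per RefSeq transcript, 33984 in each library. The values were used as deposited and taken as RPKM that the authors had scaled for depth and transcript length, by software not given in the sources used here. No label or header names their unit. It was inferred from the values to be RPKM, because value times transcript length sums to nearly the total that RPKM gives by definition in each library; RPKM and FPKM cannot be told apart here. The submitters' processing notes name STAR, DESeq2 and the build mm10, without versions or roles. The depth of a gated library was approximated from the step between its low values, which gives 65.7 M to 98.2 M reads; it is an estimate, not a deposited count. The deposited unfractionated files give a signal per gene symbol for 23420 genes, which behaves as read counts divided by 1 size factor per library, the form that DESeq2, named in the processing notes, gives: 100% of the values became whole reads within 0.01 when multiplied by that factor. These recovered reads, 21.3 M to 30.9 M per library, were expressed as CPM. A count test on them has no comparison to make, since they form a single group. In these files 27 gene symbols had been turned into dates.

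Transcripts of a gene carried nearly the same reads (median ratio of lower to higher value times length 0.941 in 1758 genes with 2 transcripts), so a gene was represented by its transcript with the highest mean over the 7 gated libraries, giving 24064 genes. Symbols and coordinates came from NCBI's table for GRCm38, the assembly that mm10 denotes, matched by RefSeq identifier for 33552 transcripts and by symbol for 305, while 127 kept the name in the file. Transcript length and GC content came from GENCODE M21 transcripts with the same RefSeq identifier.

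FSC-A High and FSC-A Low were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend) on log2(RPKM + 1), using the 7 gated libraries and the group as the only term, for genes with at least 1 RPKM in at least 3 libraries. A gene was called at a Benjamini-Hochberg adjusted p below 0.05. The comparison, the threshold, the 34 gene lists, the rule for named genes and part of the alternatives were set before the data were examined; the filter and the choice of transcript were set afterwards. The design had named a count test first, with limma on log2 values in case the files held no counts, and the second was used. Lists with at least 5 tested members were tested with camera (two-sided, preset correlation 0.01, adjusted over 29 lists), beside camera with an estimated correlation and the rotation test fry. Of the 11 calls by camera, those of the G2/M, S phase and actin and tubulin lists held with an estimated correlation, each at an adjusted p of 0.0474. Library measures were compared with two-sided exact permutation tests, which cannot give less than 0.0286 with 4 against 3 libraries.

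Named genes were the 12 largest rises and the 12 largest falls among called genes whose libraries did not overlap and whose mean log2 value was at least 4 (set for log2 CPM in the design and applied to log2(RPKM + 1)), up to 4 members of each list with the smallest p among those called (2 where none was), and the sort markers. Predicted genes, Riken clones and pseudogenes were counted and not named. Results of some single genes and of 1 gene family are not reported here, and those genes were left out of the outlier tests; the counts of genes and lists include them. The limma step was tested on simulated data for the 10619 genes with 200 genes changed. It recovered 61% of the changes of log2 size 1 and 100% of those of size 2, with 9 false calls, 5.29% of all calls. The simulated noise was independent between genes, depended only on the mean level and had no trend over length. The share of false calls in the real data may therefore differ.

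The alternatives were other scalings (median ratio, upper quartile, library total of gene values), pseudocounts of 0.5 and 5, no filter and a filter at 5 RPKM, each library left out in turn, the replicate number as a block, stricter thresholds, and the set tests named above. Chosen after seeing the data were TMM factors from edgeR 4.0.16, the sum or mean over transcripts, sample quality weights, and removal within each library of a spline (5 degrees of freedom) over transcript length and GC content or over expression level. Tables were prepared with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots with matplotlib 3.10.9.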

Results

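The series profiled haematopoietic stem cells (HSCs), the cells from which all blood lineages derive, taken from livers of wild-type C57BL/6 mice at postnatal day 0. Sorted cells were negative for lineage markers and CD48 and positive for Sca1, cKit and CD150. Between 100 and 200 of them went into each library by Smart-seq2, a full-length cDNA protocol for very small inputs. The 11 libraries fell into 3 groups. A set of 4 came from HSCs with a high forward scatter area (FSC-A High), 3 came from HSCs with a low one (FSC-A Low), and 4 came from HSCs whose labels name no scatter gate (unfractionated). Forward scatter area is a flow cytometry reading that is commonly used as a measure of cell size. The gated libraries, given in RPKM, corresponded to about 65.7 M to 85.2 M reads each in FSC-A High and 69.4 M to 98.2 M in FSC-A Low. The unfractionated libraries held 30889443, 21307178, 27206879 and 29952311 reads. The labels do not say that replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical.

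The gated libraries address how the transcripts of neonatal liver HSCs differ with forward scatter. Genes of mitosis were the most strongly raised in FSC-A High HSCs. Ube2c, a ubiquitin-conjugating enzyme that works with the anaphase-promoting complex, stood at 267 ± 32.2 RPKM (SD, n = 4) in FSC-A High and 6.48 ± 5.72 RPKM (SD, n = 3) in FSC-A Low, a log2 difference of 5.43 (SE 0.37, limma adjusted p = 8.02e-07). Birc5, which encodes survivin, a subunit of the chromosomal passenger complex, stood at 445 ± 36.2 against 14.8 ± 6.05 RPKM. In the other direction, the transcription factor genes Cebpb and Egr1 were lower in FSC-A High, at 16.9 ± 10.5 against 126 ± 40.3 RPKM and at 10.1 ± 1.67 against 82.5 ± 18.6 RPKM.

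Of 10619 genes tested with limma on log2(RPKM + 1), 1657 were higher and 1245 lower in FSC-A High at a Benjamini-Hochberg adjusted p below 0.05, together 27.3% of the genes. Of these, 798 higher and 855 lower genes changed by more than 2-fold. The libraries of both groups did not overlap in 3705 tested genes, 34.9% against 5.71% by chance, and 2719 of the called genes were among them. Across genes, Spearman's rho was 0.938 to 0.954 between FSC-A High libraries, 0.920 to 0.927 between FSC-A Low libraries and 0.862 to 0.890 between the groups. Fold changes are on the log2(RPKM + 1) scale, which understates the change of low genes. The split of calls moved with the scaling: 57.1% of the called genes were higher on the deposited RPKM scale, and 30.02% (980 higher, 2285 lower) after each library was scaled to its total of gene RPKM values. That scaling shifted the median of all genes from -0.04 to -0.31, and upper quartile scaling shifted it to -0.12.

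The 12 largest rises among well expressed genes were all of genes with known roles in mitosis or its control. After Ube2c (chromosome 2, 164769929 to 164772902 on mm10, the span of the gene) and Birc5 (chromosome 11, 117849237 to 117855743, log2 difference 4.88, SE 0.21) came Cdca3 at 4.59, Aurka at 4.48, Ccnb1 at 4.26, Nusap1 at 4.04, Cdkn3 at 3.97, Aurkb at 3.93, Plk1 at 3.79, Ccnb2 at 3.78, Cdca8 at 3.77 and Cdk1 at 3.76, with limma adjusted p values of at most 1.99e-05. Aurka, Aurkb and Plk1 are mitotic kinases, and Ccnb1 and Ccnb2 encode the cyclins that activate the kinase made from Cdk1. The 12 largest falls were a mixed set. They were Cebpb (chromosome 2, 167688915 to 167690432) at -2.94, Egr1 (chromosome 18, 34861207 to 34864956) at -2.90, Atf7ip at -2.59, Wac at -2.54, Rab35 at -2.53, Actr5 at -2.43, Mir3474 at -2.31, Dusp5 at -2.20, Pim3 at -2.18, Fgd2 at -2.01, Rnpepl1 at -1.95 and Yrdc at -1.91, with adjusted p of at most 0.00559. The microRNA entry Mir3474 (chromosome 2, 158638583 to 158638640) lies within the span of Actr5 (158624881 to 158639211), so their reads may be shared and the entry is uncertain. Without a filter on low values, Mir3474 (adjusted p = 0.0797) and Dusp5 (0.0558) no longer passed.

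**Figure D1:**
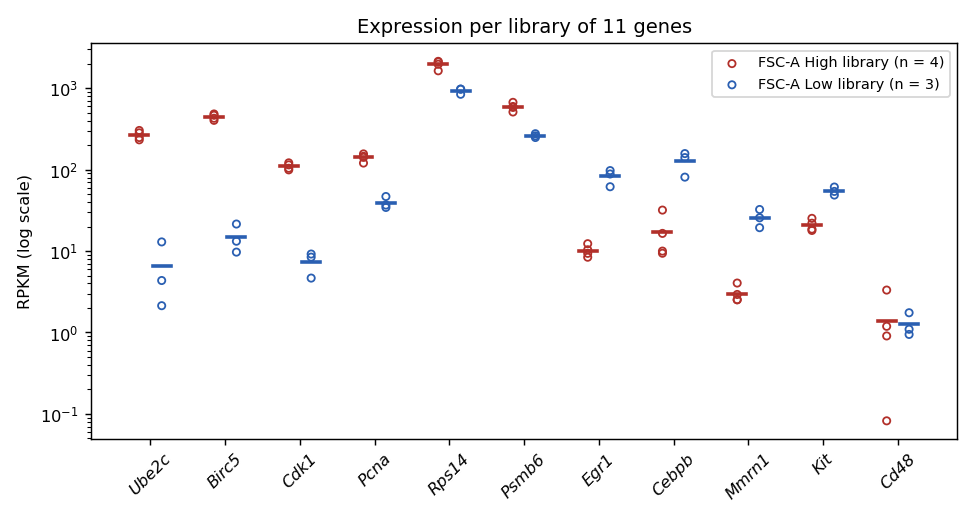
RPKM on a log scale for 11 genes in the 4 FSC-A High libraries (red circles) and the 3 FSC-A Low libraries (blue circles), with bars at the group means. Ube2c, Birc5, Cdk1, Pcna, Rps14 and Psmb6 lay higher in every FSC-A High library than in any FSC-A Low library, Egr1, Cebpb, Mmrn1 and Kit lay lower, and Cd48 overlapped.

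Genes of the cell cycle rose, those of G2/M by the largest median of any list. Of 54 measured genes of the G2/M phase list, 49 rose in FSC-A High, 1 fell and 4 did not pass, with the same counts when adjusted over the list alone. Their median log2 difference was 2.48 (camera adjusted p = 1.15e-34, adjusted p = 0.0474 with an estimated correlation). Cdc20, an activator of the anaphase-promoting complex, stood at 317 ± 22.4 against 29.9 ± 3.43 RPKM, and Cks1b, a cyclin-dependent kinase subunit, at 612 ± 24.7 against 131 ± 5.23 RPKM. Of 43 S phase genes, 25 rose, 1 fell and 17 did not pass (27 and 2 adjusted over the list alone). Their median was 0.94 (camera adjusted p = 9.04e-10, adjusted p = 0.0474 with an estimated correlation). Pcna, the sliding clamp of DNA replication, stood at 141 ± 15 against 39.3 ± 6.62 RPKM, and Gmnn, an inhibitor of replication licensing, at 120 ± 24.1 against 23.4 ± 1.28 RPKM. The members that fell, Ctcf in the G2/M list (-0.97) and Usp1 in the S list (-0.92), were named after their values were seen. The mean log2 value of the G2/M list minus that of the S list was 0.29 ± 0.08 in FSC-A High and -1.33 ± 0.29 in FSC-A Low (two-sided exact permutation p = 0.0286, the smallest that 4 against 3 libraries allow, 0.0571 after adjustment over 6 library measures).

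The nucleotide synthesis list and the actin and tubulin list were higher in FSC-A High too, though most of their members did not pass. They share members with the cell cycle lists: Tyms, Rrm1 and Rrm2 with S phase, and Tubb4b with G2/M. In nucleotide synthesis, 11 of 28 genes rose and 17 did not pass (11 adjusted over the list alone). The median was 0.42 (camera adjusted p = 0.00107, adjusted p = 0.0716 with an estimated correlation). Tk1, the thymidine kinase of S phase, stood at 102 ± 15.2 against 12.1 ± 4.91 RPKM, and Rrm2, the small subunit of ribonucleotide reductase, at 83.8 ± 6.998 against 25.7 ± 10.6 RPKM. The list's median was 0.12 with library totals as the scale and 0.20 with the trend over expression level removed. In the actin and tubulin list, 15 of 41 genes rose, 1 fell (Tln1, -1.03, named after its value was seen) and 25 did not pass (16 and 1 adjusted over the list alone). The median was 0.28 (camera adjusted p = 2.27e-04, adjusted p = 0.0474 with an estimated correlation). The members with the smallest p were the microtubule regulator Stmn1 at 529 ± 51.0 against 121 ± 1.70 RPKM, the tubulin genes Tubb4b (log2 difference 2.35) and Tubb5 (2.24), and the actin-binding Tmsb4x (1.23, or 0.51 with the length and GC trend removed). That list's call ended with the expression level trend removed (camera adjusted p = 0.444), and its median was -0.03 with library totals as the scale, where the median of all genes was -0.31.

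Inhibitors of the cell cycle went in both directions. In the list of quiescence genes and cell cycle inhibitors, 5 of 23 genes rose, 6 fell and 12 did not pass (5 and 7 adjusted over the list alone; median -0.51, camera adjusted p = 0.284). Among the risers, the inhibitor genes Cdkn2d stood at 138 ± 22.1 against 52.6 ± 8.11 RPKM and Cdkn1a at 9.13 ± 0.781 against 2.80 ± 2.09 RPKM. The other 3, Cdkn2c (1.37), Cdkn1b (1.21) and Rbl1 (1.09), were named after their values were seen. Among the genes that fell, Cdkn1c, which encodes the inhibitor p57, stood at 113 ± 14.1 against 221 ± 19 RPKM, and Rbl2, a retinoblastoma family member, at 4.49 ± 0.784 against 12.8 ± 1.30 RPKM.

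Ribosomal protein, respiratory chain and proteasome genes were higher in FSC-A High. Of 80 cytosolic ribosomal protein genes, 76 rose, none fell and 4 did not pass (79 and 0 adjusted over the list alone), with a median log2 difference of 0.90 (camera adjusted p = 2.30e-34, adjusted p = 0.152 with an estimated correlation). Rps2 stood at 354 ± 37.9 against 142 ± 4.56 RPKM. Of 77 nuclear genes of oxidative phosphorylation, 61 rose, none fell and 16 did not pass (67 and 0 adjusted over the list alone). Their median was 0.90 (camera adjusted p = 6.17e-26, adjusted p = 0.109 with an estimated correlation). Cox7a2 of complex IV stood at 252 ± 25.7 against 97.3 ± 7.77 RPKM and Uqcrb of complex III at 111 ± 14.9 against 35.1 ± 6.53 RPKM. Of 37 proteasome genes, 25 rose, 1 fell (Psme3, -0.72, named after its value was seen) and 11 did not pass (30 and 1 adjusted over the list alone). Their median was 0.72 (camera adjusted p = 1.61e-12, adjusted p = 0.109 with an estimated correlation). Psmb6, a catalytic subunit, stood at 590 ± 65.8 against 262 ± 14.1 RPKM and Psmb2 at 472 ± 77.2 against 170 ± 22.2 RPKM.

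These gains lay in short transcripts. The log2 difference fell with transcript length across 10478 genes (Spearman's rho -0.42 across genes, which are not independent replicates; -0.04 for GC content). The median length was 795 nt for the ribosomal protein genes, 765 nt for the oxidative phosphorylation genes and 1440 nt for the proteasome genes, against 2542.5 nt for the genes tested. With the trend over length and GC content removed within each library, a correction chosen after the data were seen, the medians became 0.32 for ribosomal proteins (35 of 80 genes higher), 0.37 for oxidative phosphorylation (32 higher and 3 lower of 77) and 0.48 for the proteasome (16 of 37 higher). Rps2 then had a log2 difference of 0.86 in place of 1.30, Cox7a2 0.65 in place of 1.36, Uqcrb 0.78 in place of 1.64, Psmb6 0.61 in place of 1.17 and Psmb2 0.81 in place of 1.46. The G2/M and S phase lists, with median lengths of 3085 and 3283 nt, had medians of 2.51 and 1.04 after the same correction. With library totals as the scale, the medians were 0.59 for ribosomal proteins, 0.59 for oxidative phosphorylation and 0.40 for the proteasome. With the trend over expression level removed instead, they were 0.39 (44 genes higher, 1 lower), 0.46 (44 higher, 2 lower) and 0.36 (17 higher, 1 lower).

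**Figure D2:**
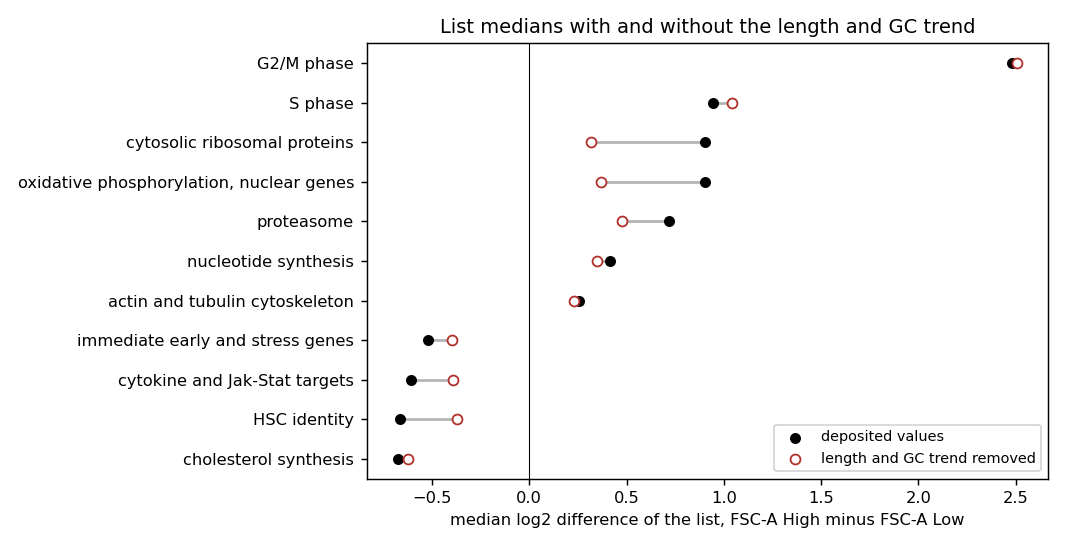
Median log2 difference, FSC-A High minus FSC-A Low, of each of the 11 gene lists past the threshold, from the deposited values (black) and with the trend over transcript length and GC content removed within each library (open red circles). The ribosomal protein median moved from 0.90 to 0.32 and the G2/M median from 2.48 to 2.51.

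Genes of HSC identity were lower in FSC-A High. Of 39 measured members, 18 fell, 4 rose and 17 did not pass (21 and 5 adjusted over the list alone), with a median log2 difference of -0.67 (camera adjusted p = 4.42e-04, adjusted p = 0.152 with an estimated correlation). Beside Egr1, Mmrn1, which encodes multimerin 1, stood at 3.01 ± 0.720 against 25.8 ± 6.52 RPKM (chromosome 6, 60944317 to 60989378; log2 difference -2.73), and Cdkn1c was lower as given above. Of the 4 members that rose, Ifitm1 (0.85), Pdzk1ip1 (0.76) and Esam (0.55) were named after their values were seen. With the length and GC trend removed, the median was -0.37, with 9 genes lower and 1 higher. Of 11 measured genes of the fetal HSC programme, 1 fell, Igf2bp2, at 25.9 ± 1.65 against 49.1 ± 6.82 RPKM (-0.89, or -0.57 with the length and GC trend removed), and 10 did not pass (1 adjusted over the list alone; camera adjusted p = 0.520).

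Cytokine signalling and immediate early genes were lower as well. Of 24 cytokine and Jak-Stat targets, 7 fell, none rose and 17 did not pass (8 adjusted over the list alone). The median was -0.61 (camera adjusted p = 4.58e-04, adjusted p = 0.109 with an estimated correlation; median -0.39 with the length and GC trend removed). Members include the kinase gene Pim3 at 20.0 ± 8.23 against 91.2 ± 26.8 RPKM and Sh2b3, an adaptor that restrains cytokine receptor signalling, at 13.5 ± 3.16 against 41.8 ± 17.9 RPKM. Of 24 immediate early and stress genes, 6 fell, none rose and 18 did not pass (6 adjusted over the list alone). The median was -0.52 (camera adjusted p = 0.00650, adjusted p = 0.109 with an estimated correlation). Beside Egr1 these included Ier2 at 171 ± 21.8 against 357 ± 48.3 RPKM, Junb at 28.5 ± 5.63 against 74.7 ± 7.83 RPKM and the phosphatase gene Dusp2 at 66.7 ± 29.5 against 198 ± 63.0 RPKM.

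Cholesterol synthesis genes fell on balance. Of 22 measured members, 9 fell, 3 rose and 10 did not pass (10 and 3 adjusted over the list alone). The median was -0.68 (camera adjusted p = 0.0131, adjusted p = 0.367 with an estimated correlation). Dhcr7, which makes the last step to cholesterol, stood at 6.85 ± 1.495 against 24.3 ± 10.9 RPKM and Lss, lanosterol synthase, at 2.95 ± 1.76 against 13.4 ± 4.52 RPKM (-1.95, or -1.21 with a pseudocount of 5). Srebf2, a transcription factor that drives the pathway, had a log2 difference of -1.21, which became -0.62 (limma adjusted p = 0.0613) with the length and GC trend removed, and Sqle one of -1.13 that did not pass without a filter on low values (adjusted p = 0.0615). The 3 that rose, Ebp (1.19), Pmvk (0.87) and Fdps (0.73), were named after their values were seen.

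**Figure D3:**
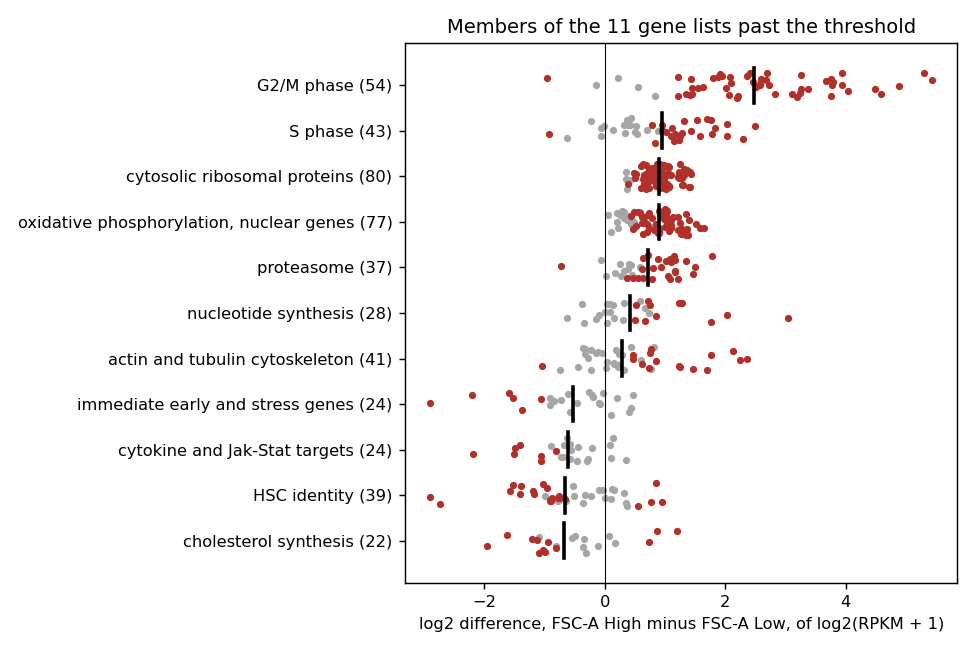
Log2 difference, FSC-A High minus FSC-A Low, of every measured member of the 11 gene lists past the threshold, with list sizes in parentheses. Red points passed the test over all genes, grey points did not, and black bars are list medians, from 2.48 for G2/M phase to -0.68 for cholesterol synthesis.

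The remaining lists of growth and metabolism did not pass as sets by camera, though single members changed. With the expression level trend removed, the glycolysis (camera adjusted p = 0.0173), endoplasmic reticulum stress (0.0173) and Myc (0.0389) lists passed as lower. Among translation factors, 13 of 40 rose and 4 fell (13 and 6 adjusted over the list alone; camera adjusted p = 0.156), from Eif3k at 338 ± 82.4 against 122.8 ± 18.3 RPKM (1.43, or 0.76 with the length and GC trend removed) to Eif4a1 at 37.0 ± 10.3 against 100.9 ± 11.1 RPKM. Among Myc and its targets, 13 of 47 rose and 9 fell (13 and 10; adjusted p = 0.596), with Ran, the GTPase of nuclear transport, at 245 ± 12.4 against 93.8 ± 7.31 RPKM. In ribosome biogenesis, 10 of 50 rose and 4 fell (10 and 5; adjusted p = 0.726; median -0.01 but mean 0.01), with Emg1 at 178 ± 25.5 against 63.9 ± 12 RPKM (1.47, or 0.89 with the length and GC trend removed) and Noc2l at 11.1 ± 3.02 against 28.6 ± 6.68 RPKM. In glycolysis, 4 of 24 rose and 5 fell (4 and 5; adjusted p = 0.520), with Gapdh at 160 ± 27.3 against 71.2 ± 4.21 RPKM (1.14, or 0.76 with the length and GC trend removed) and the glucose transporter gene Slc2a3 at 9.16 ± 2.65 against 33.9 ± 2.55 RPKM. In amino acid supply and Atf4 targets, 2 of 26 rose and 5 fell (3 and 6; adjusted p = 0.726), with Psat1 of serine synthesis at 59.2 ± 13.4 against 19.8 ± 8.04 RPKM and the glutamine transporter gene Slc1a5 at 116 ± 11.1 against 226 ± 12.2 RPKM. Among aminoacyl-tRNA synthetases 1 of 20 rose and 2 fell (1 and 1; adjusted p = 0.944). Among lysosome and autophagy genes 7 of 49 rose and 6 fell (7 and 6; adjusted p = 0.717). Among endoplasmic reticulum stress and chaperone genes none of 26 rose and 2 fell (0 and 2; adjusted p = 0.351). Lamp1, a lysosomal membrane protein, stood at 130 ± 35.4 against 266 ± 23.3 RPKM. The counts in parentheses are those adjusted over the list alone, and the p values are camera's.

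The interferon response list split. Of 43 measured genes, 9 rose, 10 fell and 24 did not pass (9 and 10 adjusted over the list alone; camera adjusted p = 0.765). The members with the smallest p all rose, and Psmb8 and Psmb9 among them are also in the proteasome list. The immunoproteasome genes were Psmb8 at 315 ± 39.7 against 140 ± 21.9 RPKM (log2 difference 1.17, or 0.68 with the expression level trend removed) and Psmb9 at 151 ± 9.84 against 70.0 ± 9.76 RPKM. The class I antigen presentation genes were B2m at 971 ± 308 against 341 ± 67.2 RPKM (1.47, or 0.69 with the length and GC trend removed) and H2-K1 at 551 ± 54.3 against 301 ± 26.2 RPKM. H2-K1 did not pass with the expression level trend removed (limma adjusted p = 0.131).

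Of the genes behind the sort, Kit fell, and the other 3 did not pass (1 lower and 1 higher adjusted over the list alone). Kit (chromosome 5, 75574987 to 75656722) stood at 20.9 ± 3.37 RPKM in FSC-A High and 54.7 ± 6.22 RPKM in FSC-A Low, a log2 difference of -1.35 (SE 0.19, limma adjusted p = 3.31e-04). Ly6a, which encodes Sca1, stood at 27.4 ± 12.6 against 12.8 ± 1.59 RPKM (adjusted p = 0.0518). It passed without FSC-A High replicate 1 (0.00476), with a filter at 5 RPKM (0.0324), with the sum over transcripts (0.0442) and with sample quality weights (0.0403). Under the other alternatives it did not pass. Its log2 difference was 0.32 in place of 0.92 with the length and GC trend removed. Slamf1, which encodes CD150, stood at 6.24 ± 2.58 against 8.83 ± 2.48 RPKM (adjusted p = 0.344). Cd48 was near 1 RPKM in both groups, at 1.37 ± 1.38 against 1.26 ± 0.426 RPKM, with a log2 difference of -0.09 whose 95% interval ran from -1.02 to 0.84.

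Markers of other blood and liver cells gave no list past the threshold. Of 16 multipotent progenitor genes, 3 rose and 13 did not pass (3 adjusted over the list alone; camera adjusted p = 0.717). Plac8 stood at 20.5 ± 6.75 against 5.45 ± 0.567 RPKM (1.69, or 0.93 with the length and GC trend removed), and Lsp1 and Emb had log2 differences of 0.51 and 0.52. Among 13 megakaryocyte and platelet genes, 5 fell and 1 rose (6 and 3 adjusted over the list alone; camera adjusted p = 0.168): beside Mmrn1, the platelet glycoprotein gene Gp5 stood at 3.13 ± 1.12 against 16.2 ± 7.95 RPKM, and Cd9 at 93.3 ± 15.4 against 31.5 ± 3.43 RPKM (1.53, or 0.99 with the length and GC trend removed). Among 12 erythroid genes, 4 rose and 1 fell (5 and 1; adjusted p = 0.282). The globin genes Hbb-bt and Hbb-b2 are near-identical copies with the same values, 151 ± 56.0 against 69.2 ± 14.3 RPKM, so they are 1 uncertain measurement. With the length and GC trend removed Hbb-bt no longer passed (limma adjusted p = 0.335). Of 6 endothelial genes, 2 fell (2 adjusted over the list alone; camera adjusted p = 0.172, and 0.0312 without FSC-A Low replicate 3), Cldn5 at 2.35 ± 1.29 against 9.28 ± 3.05 RPKM and Tie1 at 14.3 ± 0.789 against 26.2 ± 9.36 RPKM. Of 8 monocyte and macrophage genes 1 rose, Lyz2, at 232 ± 40.5 against 163 ± 0.614 RPKM (0 adjusted over the list alone; camera adjusted p = 0.156). Of 5 lymphoid genes 1 rose, Nkg7 (1 and 1 adjusted over the list alone; adjusted p = 0.780). The calls of Lsp1, Emb, Lyz2, Nkg7 and Tie1 were each lost without FSC-A High replicate 2, without FSC-A High replicate 3 and without FSC-A Low replicate 3. None of 9 hepatocyte genes passed (0 adjusted over the list alone; adjusted p = 0.944; median -0.06 but mean 0.06); Apoa1 stood at 10.96 ± 1.11 against 7.33 ± 3.93 RPKM and passed without FSC-A Low replicate 1 (limma adjusted p = 0.0445), and Apoa2 passed without FSC-A High replicate 1 (0.0289). None of 4 granulocyte genes and 1 mast cell gene passed, too few for a test of the list. The granulocyte colony-stimulating factor receptor gene Csf3r stood at 4.12 ± 1.18 against 9.45 ± 3.85 RPKM (limma adjusted p = 0.0518). It passed under 10 alternatives, among them library totals as the scale (0.0177) and without FSC-A Low replicate 3 (0.0143). Prtn3 stood at 120 ± 15.99 against 91.4 ± 3.49 RPKM and passed without FSC-A High replicate 1 (0.0270), and Hdc stood at 1.91 ± 1.77 against 3.34 ± 1.78 RPKM. No stellate or stromal gene reached the minimum level, and mitochondrially encoded genes were not analysed here.

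None of 6 library measures passed between the gated groups after adjustment (smallest adjusted p = 0.0571 by exact permutation). The exact test cannot give less than 0.0286 here, so the adjustment leaves little room to pass. The groups are therefore not shown to be alike in these measures. The 50 highest genes took 13.6% ± 0.349 of the summed RPKM in FSC-A High and 11.4% ± 0.238 in FSC-A Low (two-sided exact permutation p = 0.0286, 0.0571 adjusted over 6 measures). Genes at 1 RPKM or more numbered 10038 ± 96.7 in FSC-A High and 10352 ± 20.0 in FSC-A Low (exact permutation p = 0.0571, adjusted 0.0857), while genes above 0 numbered 13473 ± 40.2 against 13233 ± 130 (exact permutation p = 0.0286, adjusted 0.0571). The ribosomal RNA precursor Rn45s stood at 284 ± 33.9 against 403 ± 149 RPKM (exact permutation p = 0.114, adjusted 0.137). Implied reads did not separate the groups (exact permutation p = 0.686).

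The 4 unfractionated libraries give levels of HSCs with no scatter gate, in CPM, and belong to tables normalized separately from the gated ones, so no test was made between them. Transcripts of the positive sort markers were present in every library: Ly6a at 129 ± 38.5 CPM (SD, n = 4), Kit at 296 ± 163 CPM and Slamf1 at 76.3 ± 21.7 CPM. Cd48 stood at 13.7 ± 11.9 CPM and ranged from 0.200 CPM in replicate 4 to 28.9 CPM in replicate 2, without which its mean was 8.64 CPM. Birc5 stood at 181 ± 94.6 CPM, Ccnb1 at 136 ± 79.7 CPM and Egr1 at 86.9 ± 96.7 CPM. Genes chosen outside the rule for named genes were Mki67, a marker of cycling cells, at 184 ± 126 CPM, Top2a, the topoisomerase of chromosome condensation, at 212 ± 92.5 CPM, and the HSC genes Procr at 150 ± 38.7, Hlf at 231 ± 62.0 and Mecom at 108 ± 26.1 CPM. Replicate 4 stood apart, with Mki67 at 10.8 CPM, Ccnb1 at 21.6 CPM, Egr1 at 227 CPM (22.1 to 75 CPM in the others) and Kit at 537 CPM. Without that replicate the mean of Kit was 215.5 CPM. Replicate 4 also had 11384 genes above 0 against 12909 to 13368 in the others, and 15.2% of its reads came from Rn45s against 3.06% to 5.26%.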

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

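The test of other splits of the libraries, the test of length slopes, and those on other cell types and on the FSC-A Low end for replicate 4 were set before their own results were seen, though after a trial run of the comparison of gates. The tests of the length and GC correction, of CD48-positive progenitors and of depth were chosen only after the result was seen, and so was the bootstrap margin in the test of the FSC-A Low end.

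Chance is argued against as the source of the number of called genes. Of the 35 splits of the 7 gated libraries into 4 and 3, only 1, the real one, gave as many genes. It gave 2902 calls, against 312 in the highest of the others. Its share of 0.0286 is the smallest that 35 splits allow. The test cannot tell the gate from a preparation shared by the libraries of a gate.

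In a Dixon test of each group of 4 values, 8 of 137 groups had a library far from the rest. Chance gives about 1 in 20, so the total is about as many as chance would give. The total says nothing of a single library, and every flagged unfractionated group had replicate 4 as the one far from the rest. Unfractionated replicate 4 had the highest Slamf1 (108.6 CPM against 63.2 to 70.0 in the others) and Procr (207.5 against 122.8 to 136.4) and the lowest Hlf (139.2 against 254 to 276). FSC-A High replicate 1 had Noc2l at 15.59 RPKM (others 9.30 to 9.72), Rars at 29.22 (35.1 to 35.9) and Psat1 at 39.33 (63.5 to 68.1). Cdkn3 was at 57.26 RPKM in FSC-A High replicate 3 (others 71.0 to 72.4), and Fgd2 at 17.58 in FSC-A High replicate 4 (9.705 to 10.03).

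The pattern of unfractionated replicate 4 was few mitotic transcripts, with a G2/M list median of -1.51 (log2, against the mean of the other 3), and many immediate early ones, with a median of 1.496. Depth is argued against as its cause, because replicate 2, with fewer reads outside Rn45s (20.4 M against 25.4 M), had 1525 more genes above 0. RNA of other cell types stays open: the highest median among their marker lists was 0.50, in 5 endothelial genes, but replicate 1 had 0.79 for the same genes, and the monocyte (-0.54), progenitor (-0.47) and megakaryocyte (-0.44) lists of replicate 4 were lower. Cells toward the FSC-A Low end may contribute, since its deviations ran against the gated difference across 2566 called genes (Spearman's rho -0.309), which met the limit set beforehand and was the lowest of the 4; replicate 1 gave -0.30, closer than the bootstrap SE of the difference of 0.034, and that margin, added afterwards, leaves the explanation open, although the G2/M median of replicate 1 was 0.54. The list medians of replicate 4 were mixed on this. Those of ribosomal proteins (-0.43) and cytokine targets (0.33) ran against the gated difference (0.90 and -0.61). HSC identity (0.01) and cholesterol synthesis (-0.02) hardly moved, and megakaryocyte genes (-0.44) ran with it (-0.76). Each deviation is taken from the mean of the other 3, so the 4 are not independent. The labels give the 4 libraries no difference, and no biological explanation was tested beyond this.

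The rise of mitotic genes in FSC-A High may be biological, a hypothesis found and tested on the same data. A trend over transcript length is argued against as its source. The trend raised short transcripts in FSC-A High, and the G2/M transcripts were longer (median 3085 nt) than those of the genes tested (2542.5 nt). Removing the trend over length and GC content could then hardly lower the G2/M median, so its value of 2.51 afterwards adds little. A share of CD48-positive progenitors in the FSC-A High gate cannot be told apart from cycling HSCs: 3 progenitor genes (Plac8, Lsp1 and Emb) were higher, the list did not pass, and the interval of Cd48 (-1.02 to 0.84) is too wide to decide, although the sort selected against CD48. Of these genes only Plac8 kept its call across the alternatives: Lsp1 and Emb did not pass with library totals as the scale (0.20 and 0.21 in place of 0.51 and 0.52) or with the expression level trend removed (0.04 and 0.25), and Lsp1 had 0.17 with the length and GC trend removed.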

How the results depend on the processing

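Planned before the data were examined were the scalings, pseudocounts, filters, thresholds, left-out libraries, the replicate block and the other set tests; TMM, the sum and mean over transcripts, quality weights and the removal of trends were chosen after seeing the data. Of 2507 comparisons of the 120 named genes with an alternative, 2391 kept their side of the threshold, 99 lost their call, 17 gained one and none reversed. Of 631 for the gene lists these numbers were 615, 9, 6 and 1. A change of sign counted as a reversal only with a call before or after. Cd48, for example, went from -0.09 to 0.23 without FSC-A High replicate 4 and counted as kept. Among all tested genes, 6 were called in the opposite direction with the expression level trend removed. Leaving out each gated library in turn gave 1313 to 1639 higher and 868 to 1166 lower genes, 7 lists higher and 4 to 5 lower.

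The count of higher genes, 1657, became 980 with library totals as the scale, 798 with a fold above 2, 1064 at an adjusted p below 0.01 and 1026 with the length and GC trend removed (862 of them shared). The count of lower genes, 1245, became 2285 with library totals, 545 at an adjusted p below 0.01 and 781 with the length and GC trend removed (616 shared). The stricter thresholds ask more of each gene, and library totals shift every gene down; for the others the cause was not tested.

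With an estimated correlation between genes, 3 lists were higher and 0 lower: the adjusted p was 0.152 for HSC identity and for ribosomal proteins, 0.109 for oxidative phosphorylation, the proteasome, immediate early genes and cytokine targets, 0.0716 for nucleotide synthesis and 0.367 for cholesterol synthesis. The estimated correlation was 0.00917 for immediate early genes and -0.00985 for nucleotide synthesis, both below the preset 0.01. A higher correlation therefore does not account for the lost calls of these lists. The cause was otherwise not tested. Fry, which compares a list with no other genes, gave 0.0292 for translation factors, 0.0264 for glycolysis and 0.00149 for megakaryocyte genes. With the expression level trend removed, 7 lists were lower: the actin and tubulin list no longer passed (0.444), glycolysis (0.0173) and endoplasmic reticulum stress (0.0173) passed, and the Myc list, which had not passed before, passed as lower (0.0389); the cause was not tested. The endothelial list ranged from 0.0312 (without FSC-A Low replicate 3) to 0.402 over left-out libraries.

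Libraries with the same replicate number did not deviate together (correlations -0.03, 0.06 and 0.00). This gives no sign that the numbers pair the libraries but cannot exclude it, and the labels do not say. With the replicate number as a block, 1460 genes were higher and 971 lower. FSC-A High replicate 4 has no FSC-A Low library of its number, so it adds nothing to the log2 differences of that fit. These equal the differences found without it, as for Cd48 (0.229 in both). Not run were the count tests and voom (no counts for the gated libraries), a fit of all 11 libraries and the place of unfractionated means between the gated ones (different units), and scaling without mitochondrially encoded genes (none measured). Depth limits low genes: with 1 RPKM as the pseudocount, changes of genes such as Cd48 are shrunk.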

Other observations

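The gene families given here were drawn up after the results had been seen, as were the tests of the length and GC correction; the test of length slopes was set before its result was seen.

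Of 32 families of symbols, 7 were higher and 8 lower in FSC-A High by camera, and 2 of these passed with an estimated correlation. Of 78 mitochondrial ribosomal protein genes, 46 were higher in FSC-A High and none lower, with a median log2 difference of 0.64 (camera adjusted p = 1.34e-13 over 32 families, adjusted p = 0.0894 with an estimated correlation, median 0.32 with the length and GC trend removed). Mrpl33 stood at 292 ± 36.8 RPKM (SD, n = 4) against 98.0 ± 9.40 RPKM (SD, n = 3). Of 21 centromere protein genes, 4 of which are also in the lists of the report, 15 were higher (median 2.05, camera adjusted p = 3.13e-12, 0.0308 with an estimated correlation), among them Cenpa, the centromeric histone and a member of the G2/M list, at 322 ± 6.98 against 45.5 ± 10.6 RPKM. Replication-dependent histone genes were higher in 18 of 25 cases and lower in 1 (median 1.40, camera adjusted p = 1.63e-07, 0.0308 with an estimated correlation, median 1.05 with the length and GC trend removed). Many are near-identical copies whose reads can be shared. Of 24 Sm and snRNP protein genes of the spliceosome, 18 were higher and 1 lower (median 0.97, adjusted p = 9.38e-11, adjusted p = 0.0894 with an estimated correlation, median 0.45 with the length and GC trend removed), with Snrpe at 234 ± 25.1 against 80.5 ± 8.91 RPKM.

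Trim genes, which encode tripartite motif proteins, were lower in FSC-A High in 10 and higher in 1 of 28 cases (median -0.59, adjusted p = 0.00106, adjusted p = 0.0549 with an estimated correlation, median -0.29 with the trend removed), with Trim14 at 36.2 ± 15.6 against 113 ± 10.8 RPKM. Ubiquitin-specific protease genes were lower in 7 and higher in none of 36 cases (median -0.44, adjusted p = 0.00124, adjusted p = 0.0549 with an estimated correlation), and the median of -0.23 with the length and GC trend removed did not pass (adjusted p = 0.0927).

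The higher ribosomal protein, respiratory chain and proteasome genes in FSC-A High may in part reflect a bias of libraries toward short transcripts. Such a trend over length and GC content alone is argued against as the whole source. The list medians stayed at 0.32, 0.37 and 0.48 after its removal. Yet the ribosomal protein median fell from 0.90, so a large part of the difference goes with length. With the trend over expression level removed instead, the medians were 0.39, 0.46 and 0.36. The trends were never removed together, so a joint source in both stays open. Variation between libraries unrelated to the gate is argued against for the gated libraries: the slopes over length were -0.11 to -0.05 log2 per doubling in FSC-A High and 0.09 to 0.14 in FSC-A Low, a gap of 0.135 against a range of at most 0.063 within a group (two-sided exact permutation p = 0.0286, the smallest possible). What sets the slope stays open, since a preparation shared by the libraries of a gate, RNA content per cell and a real difference in short transcripts would all follow the gate. The deviations of unfractionated replicate 1 from the mean of the other 3 also ran with length (Spearman's rho 0.30 across measured genes of known length, against -0.17, -0.15 and 0.02 in the other libraries), and the ribosomal protein medians of replicates 1 to 4 were -0.51, 0.57, 0.39 and -0.43. Replicates 1 to 3 follow the length trend and replicate 4 does not, which leaves the link open.

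Sex-linked transcripts set unfractionated replicate 2 apart from the other unfractionated libraries. It had Xist at 457 CPM and the Y-linked Eif2s3y and Ddx3y at 0.329 and 0.469 CPM. The other 3 had Xist at 0.401 to 2.68 CPM, Eif2s3y at 67.5 to 124 CPM and Ddx3y at 40.4 to 81.5 CPM. All 7 gated libraries had Eif2s3y at 9.92 to 17.6 RPKM, Ddx3y at 0.824 to 5.99 RPKM and Xist at 0.794 to 2.04 RPKM. Levels in RPKM cannot be set against those in CPM.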
